A study of Homo sapiens with 4 samples.

How the data were processed

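RNA from H295R TR/SF-1 cells was compared on 4 2-colour microarrays. H295R is an established human adrenocortical carcinoma cell line, and the TR/SF-1 derivative overexpresses the nuclear receptor SF-1 (gene NR5A1) under the control of a tetracycline-responsive system. Per the labels, 2 clones were used, with 2 biological replicates per clone, and each array set basal cells against cells of the same clone and replicate after 3 days of doxycycline. Per the labels, doxycycline-treated cells were labelled with Cy5 on both replicate 1 arrays and with Cy3 on both replicate 2 arrays, so the replicate number and the dye orientation are the same thing in this design.

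The deposited values are log2 ratios, 1 per spot and array, in a table of 27648 rows. The unit was taken from the values, because the scale is not given in the sources used here. In both replicate 2 columns, 2 raised to the value was a ratio of whole numbers no larger than 65535 for 100% of rows, at a relative tolerance of 1e-13, and under 1% of rows met that condition with base e or base 10. The replicate 2 ratios are therefore ratios of scanner intensities with no further adjustment, while the replicate 1 columns are rounded and allow no such reading. The deposited log2 ratios were not centred, with medians of 0.67 and −0.51 for replicates 1 and 2 of clone 1 and 0.61 and −0.65 for replicates 1 and 2 of clone 2. The background correction, the scanner and the image software are not given in the sources used here.

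Of scale, centring and direction, the direction stays unknown: neither the labels nor the table say whether doxycycline or basal is the numerator. Whether the swapped arrays had been turned was to be decided, before the data were examined, from the correlation of the opposite-dye arrays of a clone, a clearly negative one meaning not turned. That correlation was −0.55 in clone 1 and −0.60 in clone 2 over all rows with values, control spots included, and −0.52 and −0.58 over the probes tested, yet the columns were used as already turned, which departs from the rule. The negative correlation came with a trend on spot intensity. The Spearman correlation of the value with the intensity recovered from the replicate 2 ratios was −0.68 and −0.70 on the replicate 1 arrays and 0.71 and 0.72 on the replicate 2 arrays. The mean of the orientations as deposited had heavy tails (excess kurtosis 20.7) and little relation to intensity (rho 0.12). The difference between the orientations had none (excess kurtosis −0.32) and followed intensity (rho −0.81). The counts with the replicate 2 columns turned are given as an alternative.

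Each array was centred on its median. Control spots of ACTB (321) and GAPDH (272) were averaged to 1 row each, and 26708 probes with a value on all 4 arrays were tested. The platform annotation gave exactly 1 gene symbol for 17711 rows, several for none and no symbol for 9937 rows, which are unnamed here. Symbols were updated through the RefSeq gene table, 14718 by accession and 1029 by synonym, while 1808 were current and 156 old symbols were kept. These rows name 14547 genes. No genome was used, so no coordinates are given.

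A deposited ratio of exactly 0, that is equal intensities in both channels, stood on at least 2 arrays for 130 of the probes tested and on all 4 for 57. A scanner ceiling gives such values: the 62 of these probes with a 0 on only 1 replicate 2 array had a median recovered intensity of 27040 on the other, against 483 over all probes tested. On an array with a 0, such a probe holds after centring only the array median with its sign changed and cannot show a change, while the probes with a 0 on 2 or 3 arrays keep a value of their own elsewhere. All 130 are counted as measured here. In the gene lists they were the only probes of 10 ribosomal protein genes, 4 oxidative phosphorylation genes, HSPA8, ALDOA and VIM. Intensities were recovered from ratios in lowest terms, so they are lower bounds, and every later use of recovered intensity rests on them. A ratio of 1 holds no intensity, so the other replicate 2 array was used for it, or 65535 where neither had one.

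Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. All tests were 2-sided. The design fixed before the data were examined tests the mean of the 4 arrays against 0 with no dye term (3 residual degrees of freedom). An alternative listed beforehand adds the dye orientation, that is the replicate number, as a block (2 residual degrees of freedom). The pairing by number is taken from the labels, which give both arrays of a number the same dye orientation. Arrays of 1 orientation correlated at 0.86 and 0.76 across the clones. Because the block changes nearly all calls, both results are printed, and "passed" in the text refers to the fit with the dye term unless stated otherwise. Values per clone and their difference (clone 2 minus clone 1) come from a fit with a mean per clone. With the dye term that fit has 1 residual degree of freedom and limma gave every probe a common standard error (0.11 per clone, 0.16 for the difference), so its p-values do not reflect how variable a probe is and are not printed per gene. The limma p-values rest on the spread between these 4 arrays, with the variance of a probe drawn toward a value pooled over all probes. They say nothing beyond these 4 arrays.

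Genes were named by a rule written before the data were examined. NR5A1 came first. Where fewer than 6 probes per side passed without the dye term, as here, the 10 probes of each side with the smallest unadjusted p, the same sign on all 4 arrays and 1 gene symbol followed. The clone difference names the 5 probes of each sign with the smallest p, and each gene list its 4 members with the smallest p; genes outside this rule are named where a count is small and were chosen after their values were seen. The 25 gene lists were written from textbook knowledge beforehand. They were tested with camera (preset correlation 0.01) on means over the probes of a gene, with adjustment over the lists. Estimated correlation and fry were alternatives. Camera p-values compare the genes of a list with all other genes and treat genes as nearly independent. Single list members were fitted with limma on the same means, with adjustment over 14349 genes. For a list member, "passed" refers to that fit with the dye term, in which 708 genes passed. For genes with several probes, disagreement is stated.

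Alternatives planned beforehand were quantile and scale normalization, other filters on probes, averaging probes of a gene, robust eBayes, array weights, a clone term, clone as a random block, a limit of 1.5-fold, other thresholds, an ordinary statistic without moderation, and each array left out in turn. Added after the data were seen were uncentred values, removal of a loess trend on recovered intensity (span 0.3), removal of probes with recovered intensity under 100, removal of probes with a ratio of exactly 0 on at least 2 arrays, turned replicate 2 columns, and each alternative listed beforehand combined with the dye term. The scripts were tested on simulated data with the spread of these arrays. For the mean over both clones, among 26708 simulated probes, the fit with the dye term recovered 96% of 100 probes changed by 0.5 log2 units and 100% of those changed by 1, with 2 false calls. Without the dye term it recovered 0%. For the difference between clones, 99% of 200 probes changed by 1 were recovered with the dye term, with 18 false calls. A shifted list was found and 0 other lists were called. The simulated noise was independent between probes and followed the fitted model. The simulation therefore does not show how the tests behave where genes vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.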

Results

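Gene expression in human adrenocortical H295R TR/SF-1 cells was compared between the basal state and 3 days of doxycycline, which switches on SF-1, a nuclear receptor that controls steroidogenic genes. The data were 4 2-colour arrays, 2 for clone 1 and 2 for clone 2, with the dyes exchanged between the replicates of a clone. The comparison asks which genes differ between the 2 states. No array held doxycycline-treated cells without the transgene, so effects of raised SF-1 and of doxycycline itself cannot be told apart. The number of arrays limits the precision of every value.

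The NR5A1 probe (probe 11563), which reads the SF-1 transcript, had a positive value on all 4 arrays. Its centred log2 ratio was 0.61 and 1.45 on replicates 1 and 2 of clone 1 and 0.44 and 1.10 on those of clone 2. The mean was 0.90 ± 0.08 (moderated SE of limma with the dye term, 4 arrays), with a limma adjusted p of 0.593 without the dye term and 4.4e-06 with it. The SD of the 4 values was 0.46. A moderated SE draws on a variance pooled over all probes, or over all genes for list members. Every SE below is of this kind. Signs are given as deposited, because it is not settled which state is the numerator. If doxycycline is the numerator, the positive side holds genes higher under doxycycline; if basal is, the negative side does. Whether the probe covers the part of the transcript that the transgene carries is not known, so NR5A1 does not settle it. All sides below are to be read in this way, and only if the replicate 2 columns were already turned, which is not settled. With these columns turned instead, the NR5A1 mean was −0.37 and 13358 probes passed with limma without the dye term. If that is right, a mean over the columns as deposited would hold a dye effect rather than a response.

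CCN3 and DUSP6 lay far out on the positive side, and COL18A1, FOXO4, HES6 and FATE1 on the negative side. CCN3 (formerly NOV), a matricellular protein of the CCN family, had a mean of 2.04 ± 0.09 (SE), or 4.12-fold. DUSP6, the phosphatase that inactivates ERK, had 1.68 ± 0.08. On the other side stood COL18A1, the collagen XVIII chain that gives rise to endostatin, at −2.55 ± 0.10, and FOXO4 at −2.12 ± 0.09. HES6, a HES family transcription factor, had −2.00 ± 0.12 and FATE1, a cancer-testis antigen, −1.85 ± 0.09.

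Among the other named genes on the positive side were CHAD, a cartilage matrix protein (1.48), BHLHE41, a circadian repressor (1.37), and TSPAN12, a tetraspanin (1.36). LRRC17 had 1.26, COL15A1, a basement membrane collagen, 1.14, and CDKN1A, the cyclin-dependent kinase inhibitor p21, 1.06. The other CDKN1A probe gave 1.02. FGF13 had 0.92 and CYP21A2, the steroid 21-hydroxylase, 0.90. On the negative side were CYP4F29P, a cytochrome P450 pseudogene (−2.09), SORL1, a sorting receptor (−1.60, and −0.91 at its other probe), and PPP2R5A, a regulatory subunit of protein phosphatase 2A (−1.48). APOA1, the main apolipoprotein of HDL, had −1.43, MTCL1 −1.35 and PTPRZ1, a receptor tyrosine phosphatase, −1.32. The other MTCL1 probe gave −0.01, so MTCL1 is uncertain. CYP21A2, CYP4F29P and, below, HSD3B2, AKR1C3 and MT1G have close relatives that a probe cannot be assumed to separate.

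These 20 genes were chosen by smallest p among probes with the same sign on the 4 arrays, and none passed without the dye term. In that fit, as designed, 0 of 26708 probes passed with limma, 571 had an unadjusted p under 0.05, and the smallest adjusted p was 0.139. With the dye orientation as a block, 1046 probes passed, 540 on the positive and 506 on the negative side, among them all 20 and NR5A1. With that block but without moderation of the variance, 0 probes passed, so these calls rest on the moderation. A loess correction on spot intensity, added after the data were seen, gave 148 probes without a dye term, again with all 20. The 1046 probes named 808 genes, ranged from 1.22-fold to 5.87-fold with a median of 1.33-fold, and had the same sign in both clone means, while 611 had it on all 4 arrays. Without replicate 1 of clone 1, 515 probes passed, without replicate 2 of clone 1, 1650, and without replicate 1 of clone 2, 691.

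**Figure D1:**
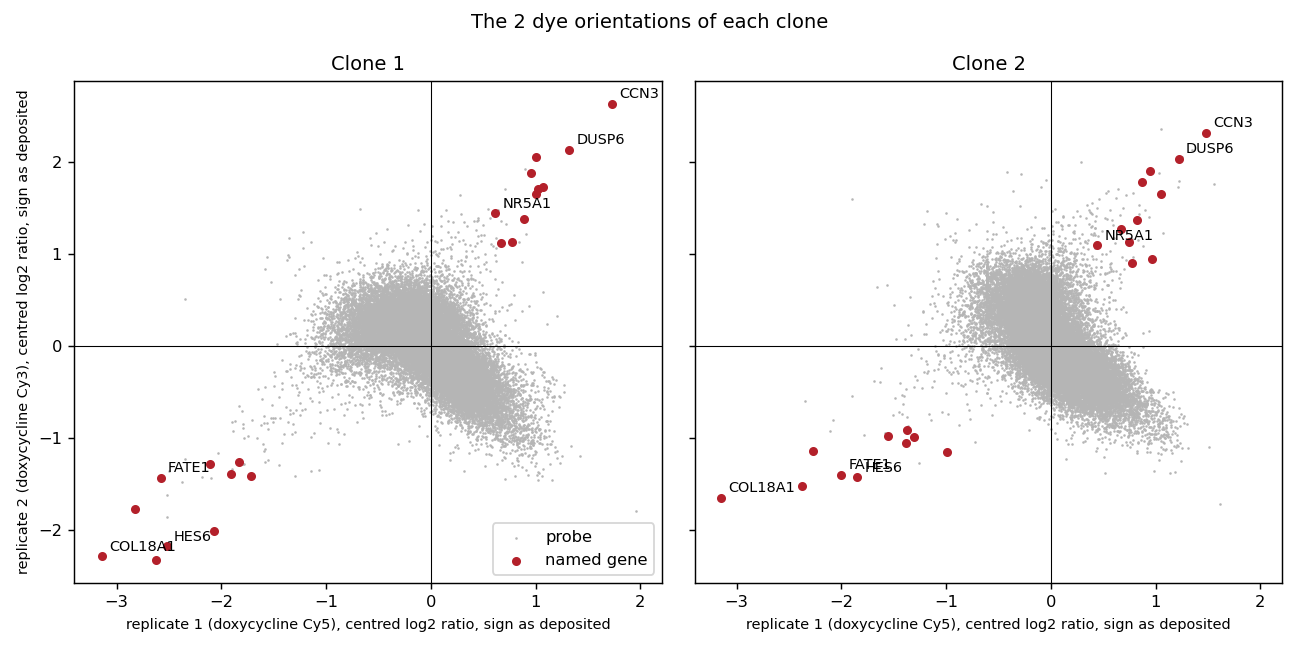
Centred log2 ratio of each probe (grey points) on the replicate 1 array (x axis, doxycycline in Cy5) against the replicate 2 array (y axis, doxycycline in Cy3) of clone 1 and clone 2, sign as deposited, with NR5A1 and the 20 named genes in red. The bulk of probes runs downward (r −0.55 in clone 1 and −0.60 in clone 2, control spots included), whereas the named genes, chosen to share a sign on all arrays, lie far out where both arrays agree in sign.

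**Figure D2:**
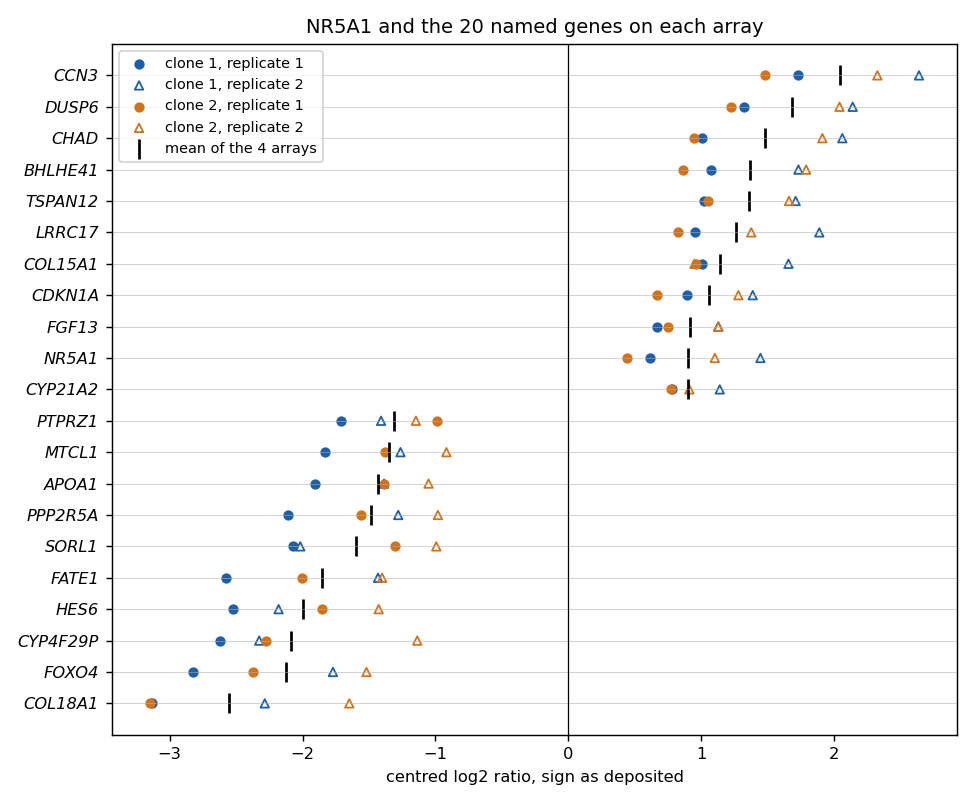
Centred log2 ratio, sign as deposited, of NR5A1 and the 20 named genes on each of the 4 arrays (circles replicate 1, triangles replicate 2, blue clone 1, orange clone 2), with the mean as a black bar. Each gene keeps its sign on the 4 arrays, as the choice of the 20 required, from COL18A1 with a mean of −2.55 to CCN3 with 2.04.

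The gene lists asked which groups of genes moved together, and 1 of 25 stood apart. Members of the amino acid response and integrated stress response list, the program of ATF4 and its targets, had a mean of 0.44 (median 0.34) over 21 measured genes, on the positive side. Its mean was −0.05 and 0.56 on replicates 1 and 2 of clone 1 and 0.40 and 0.85 on those of clone 2, and on replicate 1 of clone 1 12 of the 21 genes were below 0. In the fit with the dye term, 10 members passed on the positive side, 0 on the negative side and 11 did not pass. With p adjusted over the list alone, 15 passed, all on the positive side. The pseudokinase TRIB3 had 1.29 ± 0.14 (SE), the serine synthesis enzyme PSAT1 1.21 ± 0.17, the transcription factor DDIT3 (CHOP) 1.19 ± 0.12 and the stress-induced SESN2 0.88 ± 0.11. The camera adjusted p was 1.3e-13 without and 3.5e-11 with the dye term. With an estimated correlation the call was lost, at an adjusted p = 0.877 without and an adjusted p = 0.957 with the dye term. No other list passed with camera in either fit.

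Steroidogenic genes went both ways. Of 19 measured genes of steroid hormone synthesis, 4 passed on the positive side, which were CYP21A2, HSD3B2 (0.57 ± 0.10), the cholesterol transporter STAR (0.45 ± 0.08) and AKR1C3 (0.40 ± 0.07). Another 2 passed on the negative side, the sulfotransferase SULT2A1 (−0.94 ± 0.08) and the electron donor POR (−0.39 ± 0.07). A further 13 did not pass, and adjusted over the list alone 5 and 3 passed on the positive and negative side. STAR and AKR1C3 were below 0 on both replicate 1 arrays. Without the dye term, 0 of 14349 genes passed with limma, so every passing list member here and below rests on the dye term. Some of these members changed sign between the dye orientations, a swing that the printed SE leaves out. Of 16 genes of cholesterol uptake, storage and transport, 3 passed, all on the negative side: the sterol exporter ABCG1 (−1.46 ± 0.11), APOA1 and APOE (−0.67 ± 0.10). Adjusted over the list alone, LIPA (0.26) and STARD4 (0.26) joined them on the positive side. Of 18 cholesterol synthesis genes 1 passed, FDPS (0.59 ± 0.10, but −0.42 on replicate 1 of clone 2), and 2 did adjusted over the list alone. The mean of the uptake list was −0.13 and its median 0.08, opposite in sign.

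Among nuclear receptors and adrenal transcription factors 2 of 22 passed, both on the negative side: NR0B1 (DAX-1), a corepressor of SF-1 (−0.64 ± 0.08), and CITED2 (−0.37 ± 0.07). Adjusted over the list alone the count was the same, 2. Of 17 gonadal and pituitary SF-1 targets, 3 passed on the negative side, FATE1, the retinoic acid hydroxylase CYP26B1 (−0.94 ± 0.12) and TESC (−0.46 ± 0.08), and 2 on the positive side, the activin binder FST (0.54 ± 0.08) and LHB (0.34 ± 0.07). Adjusted over the list alone these counts were again 3 and 2. Of 20 genes of ACTH, angiotensin and cAMP signalling, 0 passed with limma in either adjustment. In that list PRKAR1A, ranked first by unadjusted p without the dye term (0.145), had 0.30 ± 0.11 and an adjusted p of 0.170 with the dye term.

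Some growth and death genes passed, where 708 of 14349 genes passed over all. Their share was not tested against that. Of 23 G1 cyclins and inhibitors, CDKN1A (1.04 over its probes) and GADD45A (0.43 ± 0.11) passed on the positive side and CCND3, cyclin D3, on the negative side (−0.71 ± 0.07). Adjusted over the list alone these 3 passed too. Of 23 apoptosis genes 1 passed in either adjustment, the BH3-only gene BBC3 (PUMA), at 0.94 ± 0.10. Of 27 DNA replication genes 0 passed and 3 did adjusted over the list alone, MCM10 (−0.37), FEN1 (−0.35) and RRM2 (−0.30), all on the negative side. Of 23 mitosis genes 1 passed in either adjustment, the kinesin CENPE (−0.46 ± 0.08), which was above 0 on both replicate 2 arrays (0.11 and 0.37). Among 17 IGF and insulin signalling genes IGFBP7 passed (0.55 ± 0.07), and IGFBP3 (0.30) joined it adjusted over the list alone.

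Matrix genes passed on both sides. Of 24 extracellular matrix and CCN genes, 3 passed on the positive side, CCN3, COL15A1 and SPP1 (osteopontin, 0.48 ± 0.08), and 3 on the negative side, COL18A1, COL11A1 (−0.48 ± 0.07) and COL4A2 (−0.31 ± 0.07). Adjusted over the list alone these counts were 6 and 3. Of 30 adhesion and cytoskeleton genes, 3 passed on the positive side, led by the integrin ITGA1 (0.88 ± 0.08), with L1CAM (0.33) and VCL (0.29), and MYH9 on the negative side (−0.64 ± 0.09), while 5 passed adjusted over the list alone. Of 29 Wnt and TGF-beta genes, 4 passed on each side. ID3 (0.51 ± 0.08), ID1 (0.41 ± 0.07), WNT4 (0.42 ± 0.07) and TGFBR3 (0.28) were positive, and SMAD7, an inhibitor of TGF-beta signalling (−0.80 ± 0.09), WNT11 (−0.43 ± 0.07), WNT5A (−0.38 ± 0.08) and TGFB1 (−0.28) negative. Adjusted over the list alone, 4 and 5 passed.

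The stress and defence lists had passing genes on both sides, where 708 of 14349 genes passed over all. Whether their share differs from that was not tested. Of 20 unfolded protein response and chaperone genes, HERPUD1 passed on the positive side (0.64 ± 0.11) and DNAJB1 (−0.61 ± 0.08), HSPH1 (−0.40) and HSP90B1 (−0.43) on the negative side, 5 passing adjusted over the list alone. Of 21 oxidative stress and drug metabolism genes, 3 passed, all positive: the metallothionein MT1G (0.72 ± 0.07), the drug exporter ABCB1 (0.65 ± 0.08) and NQO1 (0.59 ± 0.08). There were 4 adjusted over the list alone. Of 25 interferon and antigen presentation genes 1 passed, IFIT3 (0.87 ± 0.07), and 6 did adjusted over the list alone. Of 23 glycolysis and hypoxia genes, BNIP3 was positive (0.43 ± 0.09) and HK1 (−0.44 ± 0.07) and NDRG1 (−0.40 ± 0.08) negative, and 3 passed adjusted over the list alone. Of 26 nuclear oxidative phosphorylation genes 1 passed in either adjustment, SDHD (0.57 ± 0.14), but 4 of the 26 (ATP5F1A, COX4I1, COX6A1 and COX7A2) were read only by probes with a deposited ratio of exactly 0 on at least 2 arrays, which cannot show a change on those arrays. For COX7A2 that held on all 4 arrays. Of the other 22, again 1 passed. Of 25 ribosomal protein genes 3 passed in either adjustment, all positive, RPL4 (0.35), RPLP0 (0.34) and RPS3 (0.30). Of these 25, 10 were read only by such probes, 6 of them with a 0 on all 4 arrays, and of the other 15, 3 passed and 4 did adjusted over the list alone.

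Few markers of other adrenal cell types passed, where 708 of 14349 genes passed over all. Their share was not tested against that. With limma and the dye term, 0 of 10 fibroblast, 0 of 10 endothelial and 0 of 12 blood cell markers passed in either adjustment. Of 17 neuroendocrine and chromaffin markers 1 passed in either adjustment, the neurofilament NEFM (0.35 ± 0.07). The list means were 0.01 for fibroblasts, −0.0007 for endothelial cells, −0.005 for blood cells and 0.04 for neuroendocrine cells.

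**Figure D3:**
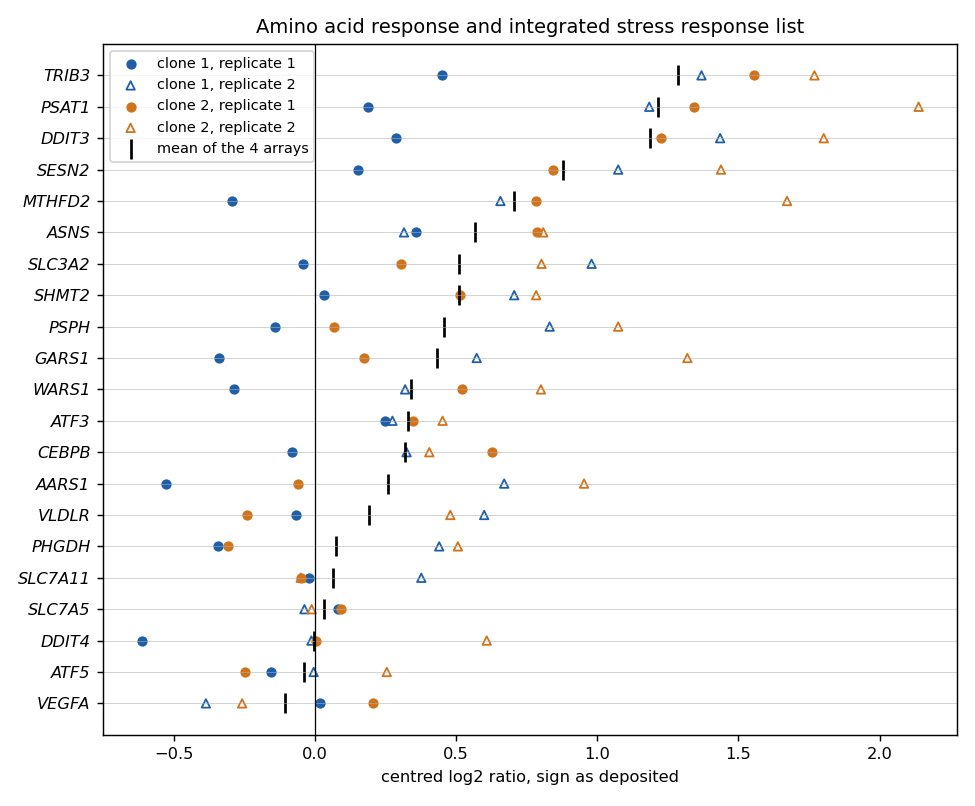
Centred log2 ratio, sign as deposited, of the 21 measured members of the amino acid response and integrated stress response list on each of the 4 arrays (circles replicate 1, triangles replicate 2, blue clone 1, orange clone 2), with the mean as a black bar. Means run from −0.10 for VEGFA to 1.29 for TRIB3, and clone 2 lies above clone 1 for 19 of the 21 genes.

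The clones were compared to see whether they shared a response. Among probes passing in a clone, clone 1 had 547 on the positive and 1092 on the negative side, and clone 2 had 984 and 367. On the positive side 264 probes were shared, where independent lists would share 20.1, and on the negative side 238, where they would share 15.0. Only 2 and 8 probes of clone 1's positive and negative side passed on the opposite side in clone 2. These calls come from the fit with the same standard error (0.11) for every probe, so they depend only on the size of a clone mean. A bias of single probes common to both clones would also raise the overlap. The overlap alone therefore does not show a shared response. CCN3 had 2.18 in clone 1 and 1.90 in clone 2, DUSP6 1.73 and 1.63, COL18A1 −2.71 and −2.40 and FATE1 −2.00 and −1.70. Across all probes the clone means correlated at r = 0.45, where probes are not independent replicates. Quantile normalization, which moved the split of the sides, gave 787 and 811 in clone 1 and 637 and 539 in clone 2, and uncentred values, added after the data were seen, gave 819 and 485 in clone 1 and 518 and 262 in clone 2. So the larger side of clone 1 depends on the centring. Without the dye term 0 probes passed with limma in either clone, and 192 and 153 had an unadjusted p under 0.05.

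Of the 25 lists, the stress response genes had the largest mean difference between the clones. In the list the mean was 0.25 in clone 1 and 0.62 in clone 2, a difference of 0.37 with a camera adjusted p of 2.6e-07 without and 3.8e-10 with the dye term. PSAT1 had 0.69 in clone 1 and 1.74 in clone 2, MTHFD2 0.18 and 1.23, and TRIB3 0.91 and 1.66. With an estimated correlation no list passed for the difference, this list and the next 4 having an adjusted p = 0.912 without and an adjusted p = 0.842 with the dye term. Without replicate 1 of clone 1 the difference was 0.07 and without replicate 2 of clone 2 it was 0.15, neither past the test; in these fits a clone keeps a single dye orientation. Unfolded protein response and chaperone genes differed by 0.29 (adjusted p of 0.0015 without and 1.3e-05 with the dye term) and DNA replication genes by 0.18 (adjusted p of 0.044 and 0.046). Mitosis genes differed by 0.22 and passed only with the dye term (adjusted p of 0.069 and 0.0033), and cholesterol uptake genes by 0.19 and passed only without it (adjusted p of 0.032 and 0.071). Without replicate 1 of clone 1 and without replicate 2 of clone 2 these differences fell to −0.052 and −0.065 for chaperones, −0.025 and −0.037 for DNA replication, −0.12 and −0.10 for mitosis and 0.026 and −0.020 for cholesterol uptake, none past the test. DNA replication, mitosis and cholesterol uptake did not pass after the loess correction with the dye term, at an adjusted p of 0.15 for DNA replication, 0.061 for mitosis and 0.12 for cholesterol uptake. No other list passed with camera for the difference.

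Of single probes, 272 passed for the difference with the dye term, 236 higher and 36 lower in clone 2, and 0 without it, where 5 had an unadjusted p under 0.05 with limma. The fit with the dye term gave every probe the same standard error (0.16), so passing there depends only on the size of the difference. Under quantile normalization the split was 62 and 54, and with uncentred values, which shift all differences alike, 17 passed. By the rule of smallest p, FSIP2 (−1.11 in clone 1 and 0.05 in clone 2), SORL1 (−2.04 and −1.15), APP (0.14 and 0.98), FBXO2 (−0.36 and 0.41) and LIG4 (−0.50 and 0.27) were higher in clone 2. ADAR (0.83 and −0.52), C6ORF185 (−0.10 and −0.97), KRTAP21-2 (0.52 and −0.24), BMP8A (0.55 and −0.14) and OR2T10 (0.45 and −0.22) were lower in clone 2. Over both clones the other APP probes gave −0.18 and −0.06, against 0.56 for the named one, so APP is uncertain.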

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

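In this part, the tests on the share of probes with the same sign, on the gene lists in each dye orientation and on NR5A1 were chosen only after the values were seen, and the loess correction was an added alternative.

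The opposite-dye arrays of a clone correlated negatively over the 26708 probes tested (mean r −0.550), while most of the probes farthest out kept their sign. An uncorrected dye effect that follows spot intensity was tested by removing a loess trend on recovered intensity, which moved the mean correlation to −0.168, so intensity carries most of it. The other explanation, that the replicate 2 columns run the other way than the replicate 1 columns, needs a response to doxycycline to change sign between the orientations and a dye effect to keep its sign. The trend on intensity changed its direction (rho −0.68 and −0.70 against 0.71 and 0.72), but this alone does not decide, since an intensity effect tied to the treated sample could reverse as well. The stress response list, taken up because it stood out, had a centred mean of 0.18 on the replicate 1 arrays (−0.05 in clone 1) and 0.70 on the replicate 2 arrays. After the loess correction these were 0.36 and 0.46, and the lower of its percentiles among 10000 random lists matched on recovered intensity was 100. For all 25 lists, compared in the same way at a level of 0.05 divided by 25, the part shared by the orientations lay outside the random lists for 1, the stress list, and the part that changes sign for 0. This could count against columns that run opposite ways only if dye effects of single probes, beyond their trend on intensity, are unrelated to gene function. The lists do not decide it, because the stress list was taken up for its high mean over both orientations. The loess correction also removes the trend on intensity, which changes sign between the orientations. The random lists treat genes as independent. With an estimated correlation, the camera adjusted p of the stress list was 0.877 without and 0.957 with the dye term. Also after the loess correction, of the 100 probes farthest from 0 on the replicate 1 array of a clone, 85 kept their sign on the replicate 2 array in clone 1 and 66 in clone 2. With 59 probes in both sets these are not independent. Together the share was 75.5%, short of the 80% first set as its bound.

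The sign of the ratios was the next pattern. NR5A1 was positive on all 4 arrays (mean 0.901), as needed if doxycycline is the numerator and the probe reads the transgene. NR0B1 (−0.64) and SULT2A1 (−0.94), which SF-1 activates, were negative, as was FATE1 (−1.85), and from what is known of this cell model FATE1 is raised and CCN3 lowered by SF-1. CYP21A2 (0.90), HSD3B2 (0.57) and STAR (0.45), steroidogenic genes that SF-1 also activates, had positive means. STAR was negative on both replicate 1 arrays (−0.006 in clone 1 and −0.195 in clone 2). These genes point the other way only if raised SF-1 increases them in this cell model, which was not tested. NR0B1, SULT2A1, FATE1 and CCN3 would make the negative side the doxycycline side, which may hold if the NR5A1 probe reads an endogenous transcript that the transgene lacks, but the 2 readings cannot be told apart here because the position of the probe is unknown and the SF-1 targets lie on both sides.

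The amino acid response and integrated stress response list lay on the positive side and 0.37 farther out in clone 2. A bias shared by probes of like intensity was tested on 10000 random lists matched on recovered intensity, whose 95% range of the difference was 0.01 to 0.18. The list stood at percentile 100, which argues against this explanation. A single deviating array was tested within each dye orientation, which holds a single array per clone. The median difference was 0.47 (95% bootstrap interval 0.19 to 0.69) on the replicate 1 arrays and 0.259 (0.08 to 0.40) on the replicate 2 arrays. These intervals can cover only the spread over the genes of the list, not the spread between arrays. Both medians were above 0, which argues against a single deviating array as well. The medians of all genes were 0.05 and 0.08, however, and the second interval starts close to that. Without replicate 1 of clone 1 the mean difference was 0.07 and without replicate 2 of clone 2 it was 0.15, in fits where a clone keeps a single dye orientation. A difference between the clones in stress or in culture was not tested and stays open.

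The other lists whose clone difference (clone 2 minus clone 1) passed in at least 1 of the fits were the unfolded protein response and chaperones (0.29), mitosis (0.22), cholesterol uptake, storage and transport (0.19) and DNA replication (0.18). Without replicate 1 of clone 1 or without replicate 2 of clone 2 these fell to between −0.12 (mitosis) and 0.026 (cholesterol uptake). With an estimated correlation none of the 25 lists passed for the difference, the adjusted p of these lists being 0.912 without and 0.842 with the dye term. For single probes, 272 passed for the difference with the dye term and 0 without it. With the dye term every probe had the same standard error (0.16), so passing depends only on the size of the difference. Among the named genes the difference passed for HES6 (0.71), CYP4F29P (0.77), SORL1 (0.89), FSIP2 (1.17), FBXO2 (0.77), LIG4 (0.76) and APP (0.84), which were higher in clone 2. It passed for ADAR (−1.35), C6ORF185 (−0.87), KRTAP21-2 (−0.76), BMP8A (−0.69) and OR2T10 (−0.67), which were lower in clone 2. All of these except HES6 and CYP4F29P were named for their small unadjusted p in this same difference. For COL15A1, replicate 2 of clone 1 stood apart from the other arrays, its gap being 0.918 of the whole range, above Dixon's 95% critical value. It was the only such case among 56 sets of values tested, where chance gives about 1 in 20.

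Other sign patterns of the 4 arrays were tried for the number of passing probes. Without the dye term the real pattern gave 0, so that all 8 patterns gave at least as many decides nothing. The highest other, 13358, was the pattern that follows the dye orientation. That points to a structure of the arrays, and the count with the dye as a block is 1046. With the dye term 1 of 7 patterns, the real one, gave 1046, and the highest other gave 0. In both cases the patterns are too few for a share under 0.05.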

How the results depend on the processing

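The uncentred, loess, dim-probe, ceiling-probe (ratio exactly 0 on at least 2 arrays left out) and turned-column alternatives, and the planned ones combined with the dye term, were chosen after the data were seen. Centring on the median was both the chosen setting and an alternative listed beforehand, so it has no separate value, and clone as a random block could not be fitted with the dye term. The number of arrays and the dye effect limit all results. Unless stated, the cause of a change was not tested.

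Without the dye term, 0 probes passed for the mean of both clones. The replicate block gave 1046, quantile normalization 8, leaving out unstable probes 72, clone as a random block 895, the loess correction 148, and turned replicate 2 columns 13358. Leaving out 1 array gave 0 to 47, highest without replicate 1 of clone 1 (47) and of clone 2 (13). The other alternatives gave 0. With the replicate block, a clone term gave 2454, at least 1.5-fold 231 (fewer probes qualify), uncentred values 574, the statistic without moderation 0, and turned columns 16235. Leaving out 1 array gave 515 to 1650, with 691 without replicate 1 of clone 2. Of the 1046 probes, 480 stayed past without replicate 1 of clone 1, 889 without its replicate 2, 628 without replicate 1 of clone 2 and 835 without its replicate 2, with 0 changes of sign.

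Of the 20 named genes, 0 passed without the dye term, 20 with the replicate block, 20 with clone as a random block, 20 after loess, 15 without unstable probes (the others were removed) and 8 after quantile normalization. Leaving out 1 array gave 0 to 18, 18 without replicate 1 of clone 1 and 12 without replicate 1 of clone 2. With the block all 20 stayed past without any 1 array, and 0 passed with the statistic without moderation. The sign of these 20 genes held in the alternatives run for them, except with turned columns. Those put all 10 genes of the positive side below 0, and with the block 8 of them passed there: CCN3 (−0.44), DUSP6 (−0.41), TSPAN12 (−0.33), BHLHE41 (−0.40), CHAD (−0.51), CDKN1A (−0.28), LRRC17 (−0.37) and FGF13 (−0.21).

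NR5A1 passed with the replicate block (0.90), and in the block with quantile (0.87) or scale normalization (0.87), uncentred values (0.93) or loess (0.84). It was past at 0.90 in the block with at least 3 arrays, without unstable or dim probes, averaged probes, robust eBayes, array weights and a clone term. Without the block it passed after loess (0.84), without unstable probes (0.90) and with clone as a random block (0.90). Leaving out 1 array gave 0.72 to 1.05, and with the block 0.81 to 0.99 (0.86 without replicate 1 of clone 1, 0.94 without replicate 1 of clone 2). Turned columns reversed it to −0.37.

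For single clones, 0 probes passed without the dye term and 1639 (clone 1) and 1351 (clone 2) with the replicate block. In clone 1, leaving out unstable probes gave 17. Leaving out 1 array gave 4 to 35 in clone 1 and 2 to 18 in clone 2. Uncentred values with the block gave 780 in clone 2. Turned columns gave 2796 and 2293 without and 9911 and 9936 with the block. The clone difference had 272 with the replicate block, and with it 116 after quantile normalization, 137 after loess, 17 uncentred and 4 with turned columns. With 1 array left out the blocked clone fits have no residual degrees of freedom, so they have no value.

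Of the 25 lists 1 passed for the mean in both fits, and the replicate block changed no other list call there. Without the block 3 passed without unstable probes, 2 uncentred, 2 with 1 probe per gene, 0 with estimated correlation and 0 with fry, and leaving out 1 array gave 1 to 4. With the block 2 passed without unstable probes, 4 with a clone term, 0 with estimated correlation and 1 with fry, which was the IGF and insulin list (adjusted p of 0.039) and not the stress list. Leaving out 1 array gave 1 to 5. For the clone difference 4 passed in each fit. Quantile normalization, scale normalization, loess and 1 probe per gene each gave 2 without the block, and quantile and loess gave 2 with it. Estimated correlation and fry gave 0 in both fits, and leaving out 1 array gave 2 to 6. In those fits a clone keeps a single dye orientation, and differences turned negative without replicate 1 of clone 1 or replicate 2 of clone 2: DNA replication to −0.025 and −0.037 (highest of the 4 fits 0.39), chaperones to −0.052 and −0.065 (highest 0.65), oxidative phosphorylation to −0.28 and −0.27 (highest 0.47), ribosomal proteins to −0.34 and −0.32 (highest 0.61), and cholesterol uptake to −0.020 without replicate 2 of clone 2 (highest 0.40). With turned columns 4 lists passed for the mean and 0 for the difference in both fits. The means were −0.26 for the stress list (no longer past), −0.46 for ribosomal proteins and −0.37 for oxidative phosphorylation, and the differences −0.046 for cholesterol uptake, −0.012 for DNA replication and −0.012 for chaperones. On arrays with a ratio of 0, probes at the ceiling hold only the centring constants, and the ribosomal and oxidative phosphorylation values rest partly on them. Without these probes the differences were −0.22 and −0.14 (highest 0.53) for ribosomal proteins and −0.23 and −0.21 (highest 0.43) for oxidative phosphorylation. Leaving them out gave 1033 probes for the mean and 270 for the clone difference with the block, and 0 for both without it.

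The mean correlation of arrays of 1 orientation across the clones was 0.80, and it was 0.72 without unstable probes and 0.62 after loess.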

Other observations

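The lists of p53, LXR and ERK targets were written after genes of each had been seen, and their tests in the present form were chosen after values of the members were seen. Members that also stood in a list written beforehand are left out of the tests.

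Some genes for feedback on ERK and some of its targets lay on the positive side beyond DUSP6. SPRED2, an inhibitor of the pathway, had 0.42 ± 0.08 (SE, dye term) and the transcription factor ETV1 0.40 ± 0.07, both passing with limma, while FOSL1 had 0.29 and PHLDA1 0.23, which did not pass. The hypothesis that the group lies on the positive side was tested on 17 measured members, without DUSP6, MYC and CCND1. Their mean, 0.13, stood at percentile 99.9 of 10000 random lists matched on recovered intensity, whose 95% range was −0.07 to 0.07. SPRY1, SPRY4, EGR1, MYC and CCND1 lay between −0.02 and 0.04. A shift of ERK output between the states is a candidate explanation, found and tested on the same data, and its direction in the cells is open with the sign of the ratios.

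CDKN1A, BBC3, SESN2 and GADD45A, all p53 targets, were on the positive side. The hypothesis that p53 targets lie there as a group was not borne out by the mean of the members tested, which leave these genes out. Such a mean does not exclude a shift of part of the group. The 15 members tested had a mean of 0.04, at percentile 71.0 of the matched random lists, and of those left out MDM2 had 0.06 and BAX 0.10. CCNG1 passed on the positive side (0.49 ± 0.11) and SESN1 on the negative side (−0.46 ± 0.09).

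ABCG1 and APOE, targets of the oxysterol receptor LXR, were on the negative side. The hypothesis that LXR targets lie there as a group was not borne out either by the mean of the members tested, which leave ABCG1 and APOE out. These 13 members had a mean of 0.004, at percentile 48.2, with SCD at 0.09, and ABCA1, left out of the test, had 0.09. PLTP alone among them passed, on the negative side (−0.45 ± 0.08).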
